A study of Caenorhabditis elegans with 5 samples.

How the data were processed

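RNA from 5 groups of worms was measured on 1-colour Affymetrix *C. elegans* arrays, 1 array per group: a 1 G ground control at the operation site, a 1 G ground control at Tsukuba space center, space flight, clinorotation and hypergravity. Per the labels, worms were frozen in liquid nitrogen, total RNA was extracted with ISOGEN, and biotinylated cRNA was made from 15 µg of total RNA. The values deposited by the authors are intensities, 1 signal per probe set on a linear scale, without detection calls. The linear scale was read from the values, which run from 0.1 to 13519 with 1 decimal. How probe cells were summarised, and with which software, is not given in the sources used here. The arrays had not been brought to a common level, since their 2 to 98% trimmed means ran from 138.9 to 217.4. The labels give the gravity of the hypergravity group both as 3 G and as 10 G, and it is therefore called hypergravity without a value.

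Probe sets were named through the GEO platform annotation, which can be older than current gene names. Of 22548 probe sets, 20766 carried 1 gene symbol, 887 carried several and 895 were not listed, and the 1782 of the last pair of classes were left out of the comparisons. Of 17118 gene symbols, 17072 were the same in the RefSeq gene table through the Entrez identifier. For 2981 genes with several probe sets the one with the highest mean over the 5 arrays was used. For 4322 genes it was a probe set that may bind several transcripts.

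The analysis was planned from the labels before the data were examined, including the scaling rule, the floor, the comparisons, the gene lists and the choice of genes to name. Because the trimmed means differed by more than 2%, arrays were quantile normalized. Signals under the 40th percentile of all scaled values (24.9) were then set to it, and log2 was taken. Genes with a mean log2 signal over the 5 arrays above the floor, 10076 of them, entered the tests. The floor stands in for a background limit, which the values do not give. The 5 arrays limit the precision of every value, because each condition has 1 array and the controls have 2.

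Each condition was compared with both ground controls in 3 ways. To begin with, limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) was fitted to all 5 arrays with the controls as 1 group, two-sided, with Benjamini-Hochberg adjusted p under 0.05. This fit has 1 residual degree of freedom, between the controls, and assumes that each lone array varies like them. Its p-values measure only the spread between these samples, whose controls come from 2 sites. Next, genes at least 2-fold above the higher or below the lower control were counted, with no test. The same count for each control against the other control and the condition gives its scale. Last, for each of 52 gene lists (42 of pathways and gene families, 10 of cell and tissue markers) the median log2 difference from the control mean was set among 10000 random lists of the same size, matched on expression deciles. A list was said to stand apart when its percentile was at most 1 or at least 99 and its median had the same sign against each control. Correlations between arrays and between conditions run across genes, which are not independent replicates. For shared changes, 100 simulated sets of 2 controls and 2 unchanged conditions were drawn, each gene with its own spread between the controls. They gave the correlation and covariance that arise without any change where arrays vary independently. The measured arrays lined up along the difference between the controls, so these values are no baseline for them. Overlaps were not compared with the simulated sets, because these had 273 genes outside both controls per condition, more than measured.

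Genes were named by a rule. Per condition and direction it takes up to 12 genes at least 2-fold beyond both controls and above the floor, ranked by distance to the nearer control, up to 3 genes at the floor on one side, up to 4 members of each list that stood apart and up to 10 shared genes per class. It also takes the members of the thick filament and myogenic factor lists, *cha-1* and *unc-17*. *ins-35* for space flight, *hsp-16.2* and *hsp-16.41* were chosen after their values were seen.

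The computations were tested on simulated data in which 200 of 10076 genes were changed. With noise like the spread between the controls, limma recovered 6% of genes changed 2-fold, 72% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. The size rule recovered 26%, 92%, 100% and 100% and took in 2.56% of unchanged genes. With the smaller spread between clinorotation and the Tsukuba control, limma recovered 92% at 2-fold and 100% from 4-fold, and the size rule 22% and 100% with 0% of unchanged genes. The spread between the controls was a root mean square over genes, and the smaller spread came from a median absolute difference, so they were not estimated alike. All simulated genes had the same SD (0.43 or 0.18, log2), whereas measured genes differ in spread and the limma prior had 2.42 degrees of freedom. The limma recoveries therefore do not hold for the measured data, where an empty limma result does not exclude large changes. Over 20 draws with no change, 1.55 lists stood apart on average and 4 at most. Random lists draw genes singly, while members of a list can move together, and lists also passed these percentiles between the controls. These draws therefore do not measure how many lists differ between untreated cultures. Alternatives covered the scaling (as deposited, centred on the median, common trimmed mean), the floor (25th and 60th percentile, none), several probe sets per gene, cross-hybridising probe sets, the fold and adjusted p thresholds, the variance model, each control left out, and a different control for each condition of a pair. The alternatives for several probe sets per gene and for cross-hybridising probe sets were not run on gene lists. The trimmed mean scaling was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.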

Results

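Gene expression was measured in whole *Caenorhabditis elegans* worms of the wild-type Bristol N2 strain on 5 Affymetrix arrays, each hybridised with labelled RNA from 1 group of 100000 worms of mixed stages. All groups had grown for 10 days at 20 °C in CeMM, a chemically defined liquid medium. The space flight group had been cultured in microgravity during the first International *C. elegans* Experiment. A clinorotation group was turned so that the gravity vector kept changing direction, a ground model of microgravity. A hypergravity group was held at a raised gravity, which one label gives as 3 G and another as 10 G. The 2 remaining groups stayed at 1 G, one at the operation site of the mission and one at Tsukuba space center, and they serve as the ground controls of every comparison. Each treatment had 1 array, so its values have no replicate of their own and carry no standard deviation. The control SD given below is that of the 2 control arrays on the log2 scale (n = 2).

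As deposited, the arrays differed in overall brightness. The trimmed mean signal, which leaves out the lowest and highest 2% of probe sets, was 147 for the operation-site control, 139 for the Tsukuba control, 217 for space flight, 177 for clinorotation and 192 for hypergravity, and median signals were 42.6, 38.8, 57.1, 46.7 and 49.2 in that order. Signals reported here are in arbitrary units after quantile scaling of the 5 arrays, with values under 24.9, the 40th percentile of all scaled signals, set to that floor. Of 17118 genes named by a probe set, 10076 had a mean signal above the floor.

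Sperm genes separated the 5 worm populations more than any other gene group measured. The median signal of 43 genes expressed in sperm, among them those of the major sperm proteins, was 500.1 in the operation-site control and 572 in space flight, against 155 in the Tsukuba control, 109 in clinorotation and 179 in hypergravity. *msp-3*, which encodes a major sperm protein, read 1643 and 1565 in the operation-site control and space flight and 448, 307 and 442 in the Tsukuba control, clinorotation and hypergravity. The inducible heat shock gene *hsp-70* ran the other way, at 1769.7 and 2317 in the operation-site control and space flight and at 8000.3, 8549 and 7877 on the remaining arrays. The 2 ground controls thus differed from each other, although both were kept at 1 G: 474 genes were at least 2-fold higher and 414 at least 2-fold lower at the operation site than at Tsukuba, 888 in all.

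The difference between the controls covered 14 of the 52 gene lists at a percentile of at most 1 or at least 99 among 10000 random lists of matched size and expression. Sperm genes were higher at the operation site by a median of 1.83 (log2), with 41 of 43 members higher. Genes of pharyngeal muscle were higher by 1.13, insulin-like peptide genes by 0.69, genes of glutamate signalling by 0.45, targets of the transcription factor DAF-16 by 0.37, genes of DNA repair by 0.36, ABC transporters by 0.27, neuropeptides by 0.23 and C-type lectins by 0.22. Small and inducible heat shock genes were lower at the operation site, with a median of -0.85, as were hedgehog-related genes (-0.57), autophagy genes (-0.41), constitutive and organelle chaperones (-0.33) and histones (-0.32). The first principal component of the genes above the floor took 65.1% of the variance and placed the operation-site control (loading 0.53) with space flight (0.56), apart from the Tsukuba control (-0.39), clinorotation (-0.38) and hypergravity (-0.33). The second component, with 19.2% of the variance, set hypergravity (-0.70) and space flight (-0.34) apart from the controls (0.40 and 0.44) and clinorotation (0.20). Across genes, which are not independent replicates, log2 signals of the operation-site control correlated with space flight at r = 0.979 and with the Tsukuba control at r = 0.941, and those of the Tsukuba control with clinorotation at r = 0.986. Because the controls differ, a gene is counted below only where the treated array lay outside both of them, and the medians of gene lists are given against each control. The labels do not say where the clinorotation and hypergravity groups were grown.

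**Figure D1:**
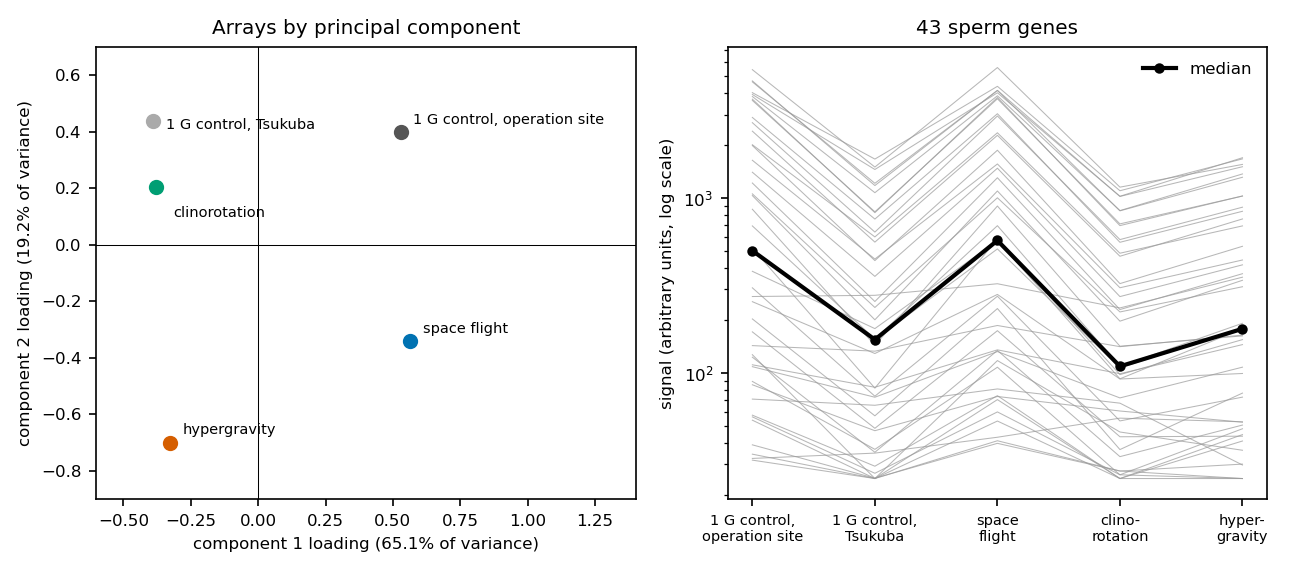
Left, loadings of the 5 arrays on principal components 1 and 2 of the genes above the floor, 1 point per array. Right, signals (arbitrary units, log scale) of 43 sperm genes on each array, with thin lines linking the values of one gene and the black line showing the median, which is 500.1 and 572 in the operation-site control and space flight and 109 to 179 on the other 3 arrays.

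The comparison of space flight with the ground controls asks which genes of the worm differ after culture in microgravity, with muscle as a main interest. Genes of body wall muscle, cuticle and epidermis were lower in space flight than in both controls, and genes of the germ line were higher. Of 11 measured body wall muscle markers, 10 lay below both controls, by a median of -0.34 (log2) from the control mean. Of the cuticle collagen genes measured, 72 lay below both controls and 1 above both, with a median of -0.41. Of 26 oocyte and germ line genes, 24 lay above both controls and 0 below, with a median of 0.38. These differences were mostly under 2-fold for a single gene.

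Within muscle, genes of the contractile filaments and of their attachments were lower on median. Of 11 thick filament genes, all were below the control mean and 8 below both controls, with a median of -0.44 against the operation site and -0.26 against Tsukuba (percentile 0.24). *unc-54*, the major myosin heavy chain of body wall muscle, read 1673 in space flight against 2208 and 2044 in the operation-site and Tsukuba controls, 0.29 below the nearer control with a control SD of 0.08. *myo-3*, the second body wall myosin heavy chain, read 241 against 306 and 333, and paramyosin, *unc-15*, 2212 against 2730.0 and 2706. The essential light chain gene *mlc-3* read 2020.2 against 2741 and 3089, and the pharyngeal myosin gene *myo-1* 324 against 814 and 427. The regulatory light chain genes *mlc-1* (1578 against 1776 and 1705) and *mlc-2* (7765 against 9418 and 9308) and the giant muscle protein gene *unc-22* (96.95 against 195 and 111) were also below both, while *myo-2*, *ttn-1* and *unc-89* lay between the controls. Second probe sets put *unc-22* between the controls and *ttn-1* below both. Of the other probe sets of *unc-89*, one lay below both (94.1 against 101.5 and 120.4), one above both (38.4 against 24.9 and 25.7), one between them and one at the floor. Of 17 thin filament genes, 10 were below both controls, with medians of -0.37 against the operation site and -0.19 against Tsukuba. The troponin T genes *tnt-2* (784 against 1193 and 1649) and *tnt-3* (111 against 207 and 196), the troponin I gene *tni-1* (203 against 262 and 587) and *unc-87*, a calponin-related thin filament protein (1638 against 2375 and 2461), were the farthest outside. Of 15 genes of dense bodies and muscle attachment, 13 were below both controls, with a median of -0.45, and these included the integrin gene *pat-2* (82.8 against 129.6 and 173), the alpha-actinin gene *atn-1* (266 against 382 and 383), *unc-96* (82.7 against 128 and 123) and the zyxin gene *zyx-1* (462 against 661 and 801). All 11 body wall muscle markers, 8 of the 11 thick filament genes and 7 of the 17 thin filament genes are also members of other lists, so these medians are not separate evidence. The muscle transcription factor *unc-120* read 97.9 against 116 and 153, while the MyoD homologue *hlh-1* and *hnd-1* were at the floor on the space flight array and both control arrays. Of the 2 genes for making and loading acetylcholine, *cha-1* read 42.4, between the controls at 45.5 and 36.3, on one probe set and 32.2 against 54.1 and 50.8 on another, and *unc-17* read 41.6 against 56.7 and 58.6, with another of its probe sets next to the lower control (37.2 against 37.5 and 55.1) and a further one below both (33.9 against 58.4 and 62.8).

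Genes of the skin of the worm were lower as well, relative to all genes. Collagens made up 9 of the 52 genes at least 2-fold below both controls. *col-85* read 174 against 472 and 1264, *col-45* 52.4 against 157 and 339.7, *col-102* 167 against 476 and 984 and *col-2* 489 against 1148 and 2256. Hedgehog-related genes, most of which are expressed in the epidermis, had the lowest list median from the control mean in space flight, at -0.66. It ran from -0.91 to -0.35 over the settings of the processing, each control alone included. Of 48 members 39 were below both controls and 2 above. *grl-23* read 104.4 against 240.3 and 843 and *grl-7* 52.6 against 107 and 126. Of 14 moulting genes, 11 were below both controls (median -0.43), among them *mlt-8* (60.5 against 139 and 135) and *noah-1* (318 against 543 and 566). Of 11 hypodermis markers, 8 were below both (median -0.33), among them the collagen genes *rol-6* (128 against 268 and 253) and *dpy-7* (63.8 against 115 and 223) and the epidermal transcription factor *elt-3* (307 against 437 and 475). Of these markers 7 of 11, and of the moulting genes 4 of 14, are also members of other lists, so these medians are not separate evidence. Of 40 antimicrobial effector genes 17 were below both and 2 above (median -0.14), led by the epidermal peptide genes *nlp-30* (54.6 against 187 and 134), *nlp-33* (127 against 268 and 268) and *nlp-31* (226 against 555 and 426).

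Neuropeptide genes, a list that also holds those 3 peptides, had a median of -0.24 with 45 of 74 below both controls and 5 above, and pan-neuronal markers a median of -0.22 with 9 of 16 below both, standing apart in 4 of 9 settings of the processing. *egl-3*, the convertase that cuts neuropeptide precursors, read 2149 against 3044 and 2859.6, and *nlp-53* 76.3 against 155 and 145. Of 63 genes of fat metabolism, 33 were below both controls and 11 above (median -0.22), with the acyl-CoA synthetase genes *acs-5* at 233 against 606 and 451 and *acs-17* at 287 against 505 and 542. Autophagy genes had a median of -0.24, which ran from -0.48 to -0.0015 over 9 settings of the processing, each control alone included. Of 24 members 10 were below both controls and 3 above, and *epg-7* read 125 against 153 and 202. Intermediate filament genes, several of which are intestinal, had a median of -0.31 with 8 of 11 below both controls, *ifc-1* among them at 65.3 against 142 and 89.8. Both lists stood apart in 5 of 9 settings.

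In the other direction, germ line genes were modestly higher. *htp-1*, a component of meiotic chromosome axes, read 762 against 549 and 415, the synaptonemal complex gene *syp-1* 387 against 296 and 283, and the maternal regulators *pie-1* 409 against 304 and 273 and *spn-4* 1718 against 1271 and 1315. Of 28 genes of DNA damage response and repair, 20 were above both controls and 0 below (median 0.28), among them *brc-1* (109 against 79.9 and 71.9) and *brd-1* (161 against 127 and 129), the worm counterparts of BRCA1 and BARD1, and the helicase gene *him-6* (195 against 151 and 117). Sperm genes lay 0.09 above the operation-site control and 1.81 above the Tsukuba control, with 34 of 43 above both. Of 60 C-type lectin genes, 29 were above both and 13 below (median 0.28), with *clec-18* at 315 against 85.2 and 63.05, *clec-57* at 106 and 2.07-fold above the nearer control (a second probe set 0.32 above in log2) and *clec-60* at 1526 against 1036 and 407.

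By size alone, 70 genes of 17118 lay at least 2-fold outside both controls in space flight, 18 above and 52 below. The gene farthest above was *Y51B9A.8*, at 3188 against 761 and 311, a 4.19-fold distance to the nearer control. It was followed by *F35E8.7* (471 against 125 and 43.2), *clec-18*, *T25B9.8* (207 against 66.6 and 48.9, with a second probe set at 64.9 against 37.1 and 47.6), *F35E8.6* (764 against 263 and 27.7), *Y26D4A.21* (134 against 48.6 and 35.5) and *rrn-3.56*, a ribosomal RNA gene (123 against 55.2 and 39.6). *F47B8.4*, *cash-1* and the initiation factor gene *eif-3.H* were at least 2-fold above the nearer control (55.8 against 27.6 and 27.9 for *eif-3.H*), though a second probe set of *cash-1* lay 0.40 above it (93.7 against 66.9 and 71.2), and *clec-128* read 109.6 with the Tsukuba control at the floor. Farthest below were *F15E6.3* (27.6 against 100.02 and 84.97; a second probe set of this gene was at the floor, with controls at 35.5 and 56.4), *col-45*, *F38B7.2* (144 against 425 and 531), *col-102*, *col-85*, *T26C12.2* (28.5 against 74.9 and 241) and *C28H8.5* (36.7 against 93.8 and 99.1). *scl-11* read 280.3 against 685 and 1298, the nuclear hormone receptor gene *nhr-53* 32.8 against 79.9 and 129, *bcmo-1* 51.6 against 122.4 and 214 and *Y42A5A.3* 103.7 against 246 and 245. The insulin-like peptide gene *ins-35*, chosen after its values were seen, read 245 against 559 and 763.

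No gene passed limma at an adjusted p under 0.05 in space flight. At an unadjusted p under that threshold there were 144 genes, where 503.8 would be expected by chance, and the smallest adjusted p was 0.970. For *Y51B9A.8* the difference from the control mean was 2.71 ± 0.63 (log2, SE, limma) with an adjusted p of 0.970, above both controls. For scale, the operation-site control lay 2-fold outside the Tsukuba control and space flight at 55 genes (35 higher, 20 lower), and the Tsukuba control outside the operation-site control and space flight at 607 (292 higher, 315 lower). Of unchanged genes in simulated data, 2.56% met the rule with the spread between the controls and 0% with the smaller spread between clinorotation and the Tsukuba control, so how many of the 70 chance would give depends on the spread assumed. These spreads were estimated in different ways, so part of that contrast can come from the estimate. In all, 18 of 52 lists stood apart in space flight, 4 higher and 14 lower, against a mean of 1.55 and a highest count of 4 in 20 simulated sets with no change, and against 14 lists past the same percentiles between the controls themselves. Since 14 lists passed between untreated cultures, the simulated counts do not show how many lists differ without treatment. Against the Tsukuba control alone 12 of the 18 still did, and the lists of thick filament (-0.26), thin filament (-0.19), body wall muscle (-0.29), hypodermis (-0.33), intermediate filament (-0.36) and pan-neuronal genes (-0.13) did not. Against the operation-site control alone 12 did, and the lists of DNA repair (0.16), C-type lectin (0.08), moulting (-0.25), intermediate filament (-0.24), sperm (0.09) and autophagy genes did not. Without scaling, the median of all genes was 0.62 higher in space flight than in the controls, so that 365 genes were higher and 2 lower at 2-fold, and 15 of the 102 genes named for this comparison, among them *unc-54*, *unc-15*, *myo-3*, *mlc-1*, *mlc-2*, *atn-1*, *unc-120*, *elt-3* and *egl-3*, then lay above the nearer control (*unc-54* by 0.14, *unc-15* by 0.21 and *myo-3* by 0.25), so that their lower values hold relative to all genes only. Centring each array on its median gave 26 higher and 30 lower, and scaling to a common trimmed mean 13 higher and 61 lower.

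**Figure D2:**
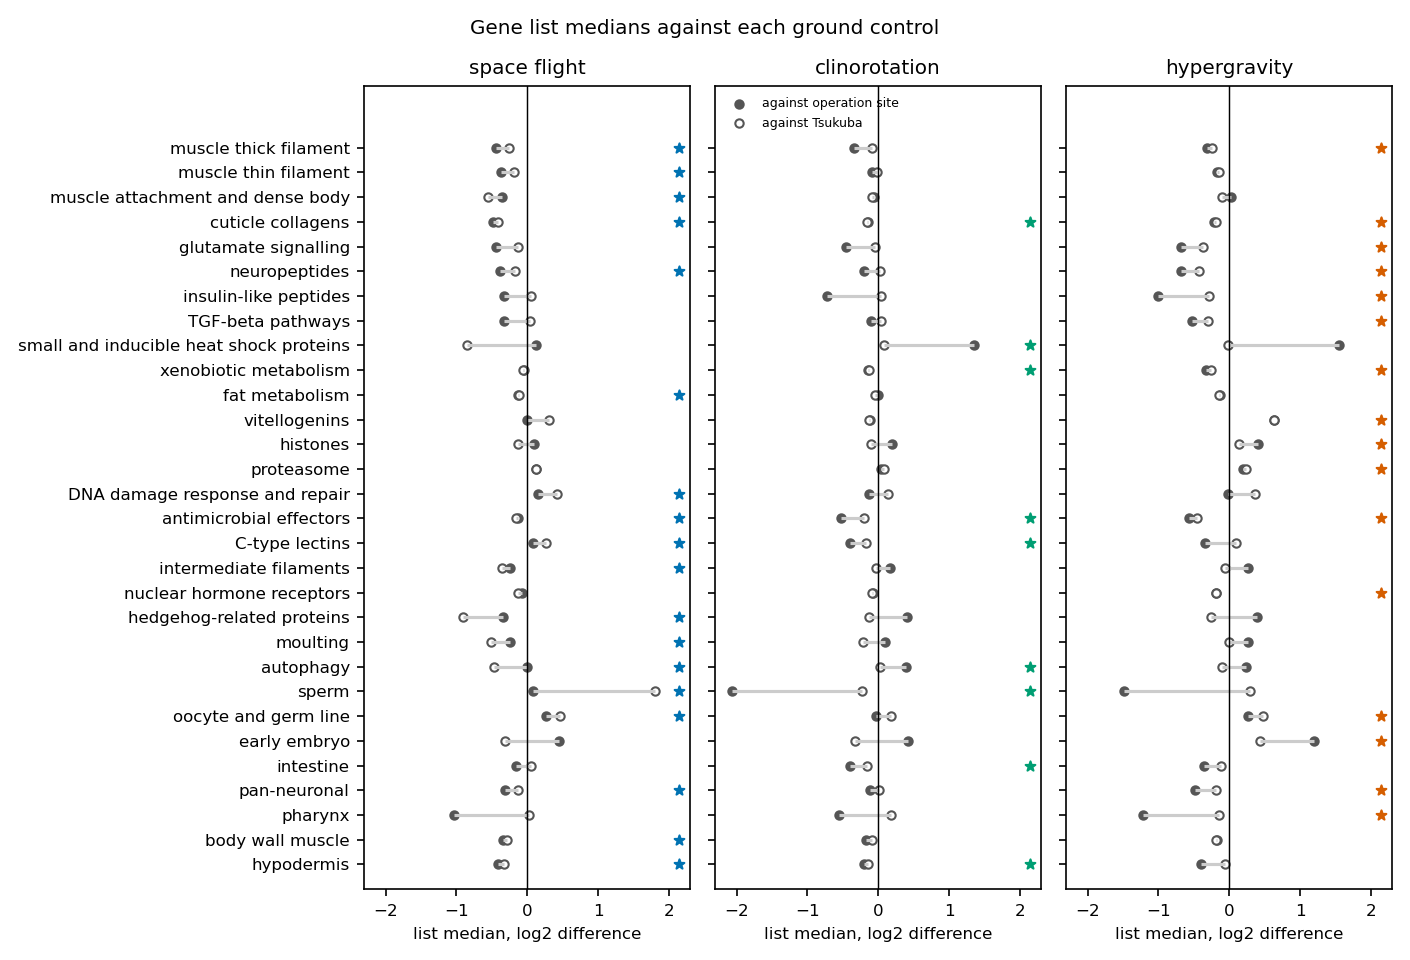
Median log2 difference of 30 gene lists from each ground control for space flight, clinorotation and hypergravity, with filled points against the operation-site control, open points against the Tsukuba control and a star where the list stood apart. Body wall muscle genes in space flight lie at -0.34 and -0.29, while sperm genes lie at 0.09 and 1.81.

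The comparison of clinorotation with the ground controls asks what a changing gravity vector does on the ground. Few genes lay outside both controls: 12 were at least 2-fold higher and 3 at least 2-fold lower. *F22B5.4* was the farthest above, at 432 against 82.9 in the operation-site control and 102 in the Tsukuba control, a 4.22-fold distance to the nearer one with a control SD of 0.21. *H39E23.3* was the farthest below, at 1259.9 against 3270.4 and 3442, with a control SD of 0.05. Antimicrobial effector genes, C-type lectin genes and intestinal markers were lower on median than in both controls and stood apart. Body wall muscle markers did not stand apart, with a median of -0.11 and 5 of 11 below both. The lists were not tested against each other.

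Among genes of immune defence, 23 of 40 antimicrobial effectors were below both controls and 5 above, with a median of -0.42. The caenacin gene *cnc-8* read 163 against 298 and 271, the saposin-like gene *spp-8* 537 against 892 and 904, *fipr-24* 114 against 352 and 186 and *nlp-31* 273 against 555 and 426. C-type lectins had a median of -0.32, with 28 of 60 below both controls and 10 above, and included *clec-50* (285 against 526 and 506), *clec-72* (53.9 against 101 and 93.8), *clec-265* (89.6 against 493 and 144) and *clec-18* (35.3 against 85.2 and 63.05). Of 12 intestine markers, 7 were below both and 0 above (median -0.25). The gut esterase gene *ges-1* read 153 against 409 and 277, the protease gene *cpr-1* 819 against 1755 and 1143 and the peptide transporter gene *pept-1* 101 against 205 and 126. Of the genes of xenobiotic metabolism, 53 were below both and 28 above (median -0.11), with *ugt-44* at 121 against 399 and 241.

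Cuticle collagens had a median of -0.20, with 51 members below both controls and 16 above, and *rol-6* read 160.1 against 268 and 253. *col-129* read 51.1 against 412 and 84.8 and *col-38* 36.6 against 286 and 59.8. Hypodermis markers had a median of -0.25, with 5 of 11 below both and 3 above, *col-12* among them at 1362 against 2101 and 1757. As said above, these markers overlap with other lists. Sperm genes were 2.06 below the operation-site control and 0.23 below the Tsukuba control as medians, the 32 members below both controls including *msp-32* (92.6 against 381 and 179), *gsp-4*, a sperm phosphatase (36.5 against 204 and 56.9), and *msp-65* (1100.5 against 4001 and 1669). Small and inducible heat shock genes, a list that stood apart in 5 of 9 settings, were 1.35 above the operation-site control and 0.09 above the Tsukuba control as medians, with *hsp-12.6* at 1551 against 609 and 1058 and *hsp-17* at 1509 against 486 and 1184. Autophagy genes had a median of 0.19 with 13 of 24 above both controls and 1 below, *atg-16.1* among them at 77.2 against 48.3 and 62.4.

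In muscle, *unc-54* read 1929 against 2208 and 2044, *unc-15* 2431 against 2730.0 and 2706 and *myo-3* 241 against 306 and 333, while *mlc-2* read 9933 against 9418 and 9308. Without scaling *unc-54*, *unc-15* and *unc-17* lay 0.10, 0.12 and 0.085 above both controls. Thick filament genes had a median of -0.16 and did not stand apart (percentile 1.34). *unc-120* read 186 against 116 and 153 and *hlh-1* 32.3 with both controls at the floor. *cha-1* (40.02) lay between the controls on one probe set and 2-fold below both on another (25.2 against 54.1 and 50.8), and *unc-17* (53.5) just below them, or between them on another probe set (50.1 against 37.5 and 55.1). The other genes at least 2-fold above both controls, with the signals of clinorotation and both controls above the floor, were *grsp-4*, which encodes a glycine-rich secreted protein (110.3 against 40.2 and 38.2), *rrn-3.56* (149.5 against 55.2 and 39.6), *T25B9.8* (152 against 66.6 and 48.9, with a second probe set under 2-fold at 66.6 against 37.1 and 47.6), *C06E2.5* (86.4 against 38.2 and 37.6), *B0478.3* (77.1 against 28.97 and 34.1) and the nucleotide excision repair gene *xpc-1* (101, or 2.05-fold above the nearer control). *fbxa-14*, an F-box gene (44.6 against 179 and 95.1), and *Y17G7B.8* (90.1 against 202 and 183) were at least 2-fold below both.

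No gene passed limma at an adjusted p under 0.05 in clinorotation, 33 did at the unadjusted threshold where chance gives 503.8, and the smallest adjusted p was 1.00. For *F22B5.4* limma gave a difference of 2.23 ± 0.33 (log2, SE) with an adjusted p of 1.00. Set beside these 15 genes, the Tsukuba control lay 2-fold outside the operation-site control and clinorotation at 21 genes, and the operation-site control outside the Tsukuba control and clinorotation at 628. Of the 52 lists, 9 stood apart, 2 higher and 7 lower. Against the Tsukuba control alone the heat shock (0.09), autophagy (0.02) and hypodermis (-0.15) lists no longer did, and against the operation-site control alone the hypodermis list (-0.19) did not. Other lists came in, so that 15 passed the percentiles against the Tsukuba control alone and 17 against the operation-site control alone. The 2-fold count was 56 genes against the Tsukuba control alone and 916 against the operation-site control alone. Without scaling, where the median of all genes was 0.29 higher in clinorotation, 36 genes were higher and 1 lower, centring on the median gave 16 and 5, and the trimmed mean 9 and 8.

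The comparison of hypergravity with the ground controls asks what a raised gravity does, at the opposite end of the scale from space flight. Genes of neuropeptides and glutamate signalling were lower than in both controls, and genes of yolk, oocytes and the proteasome were higher. Of 74 neuropeptide genes, 62 lay below both controls and 7 above, with medians of -0.68 against the operation site and -0.43 against Tsukuba. All 5 vitellogenin genes, which encode yolk proteins made in the intestine of egg-bearing worms, lay above both controls, with a median of 0.76. Of 33 proteasome genes, 24 were above both controls and 2 below, with a median of 0.25.

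Among neuronal genes, the FMRFamide-like peptide gene *flp-18* read 497 in hypergravity against 1398 in the operation-site control and 1025 in the Tsukuba control, *nlp-14* 93.4 against 207 and 195, *nlp-2* 30.1 against 65.3 and 63.8 and *nlp-91* 25.2 against 74.7 and 53.6. Pan-neuronal markers had a median of -0.40 with 12 of 16 below both controls. The synaptotagmin gene *snt-1* read 75.8 against 171 and 216, the SNAP-25 gene *ric-4* 241 against 577 and 420.3, *rab-3* 134 against 323 and 204 and *egl-3* 1764 against 3044 and 2859.6, though a second probe set of *egl-3* lay between the controls (1498 against 1384 and 1622). Genes of glutamate signalling had a median of -0.49, with 12 of 17 below both controls and 0 above, including the glutamate-gated chloride channel gene *glc-1* (130.3 against 369 and 259), the transporter gene *glt-1* (182 against 404 and 334) and the receptor gene *glr-5* (29.8 against 85.5 and 54.3). The lists of cholinergic, GABA and monoamine signalling, potassium channels, mechanosensation and chemoreceptors did not stand apart (medians -0.10, -0.38, -0.20, -0.21, -0.06 and -0.04). Insulin-like peptides had a median of -0.66 with 9 of 15 below both, though -1.01 against the operation site and -0.29 against Tsukuba. *ins-35* read 428 against 559 and 763 and *ins-33* 80.4 against 118.9 and 144. Of 15 genes of the TGF-beta pathways, 12 were below both controls and 0 above (median -0.39), among them the dauer pathway ligand *daf-7* (91.4 against 144 and 135), *daf-3* (328 against 636 and 454) and *sma-9* (444 against 763 and 565). A second probe set of *daf-3* lay just below the controls (207.9 against 223.6 and 254.0).

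Yolk and egg genes went the other way. *vit-5* read 2699 against 1503 and 1541, *vit-4* 2730.0 against 1753 and 1797, *vit-6* 8025 against 5271 and 4250.2 and *vit-1* 184 against 82.7 and 118.9. Of 26 oocyte and germ line genes, 20 were above both controls and 1 below (median 0.36), including *cgh-1* (2303 against 1190.0 and 1387, with a second probe set between the controls at 1035.0), *oma-2* (1944 against 1205 and 1124), *spn-4* (2114 against 1271 and 1315) and *mex-3* (1183 against 797 and 691). Both measured early embryo genes were higher (median 0.82), *end-1* at 56.4 against 25.8 and 38.6, and this list stood apart in 4 of 8 settings. Sperm genes did not move with them and lay 1.48 below the operation-site control and 0.30 above the Tsukuba control. The proteasome genes *pas-7* (749.7 against 485 and 479), *pbs-3* (1394 against 982 and 979.8), *rpn-7* (2076 against 1183 and 1406) and *rpt-6* (481 against 364 and 370.3) belong to both the core and the regulatory particle. A second probe set of *pbs-3* lay just above the controls (545.9 against 523.6 and 531.6). Of 22 histone genes, 16 were above both controls and 1 below (median 0.27), with *his-1* at 567 against 269 and 385.

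Several gene families of detoxification, defence and cuticle were lower in hypergravity. Genes of xenobiotic metabolism had a median of -0.33, with 62 members below both controls and 23 above. *ugt-8* read 63.7 against 227 and 222, *ugt-66* 171 against 433 and 467 and the glutathione transferase gene *gst-4* 164 against 332 and 328. Antimicrobial effectors had a median of -0.49, with 27 of 40 below both and 4 above, *spp-8* reading 319 against 892 and 904 and *fipr-24* 62.7 against 352 and 186. Nuclear hormone receptor genes had a median of -0.18, with 73 of 134 below both and 23 above, including *nhr-34* (235 against 400.4 and 378) and *nhr-63* (25.3 against 44.8 and 54.2). Cuticle collagens divided, with 44 members below both and 17 above and a median of -0.13. *sqt-2* (42.8 against 151 and 127), *sqt-1* (87.6 against 259.6 and 221), *rol-6* (94.4 against 268 and 253) and *dpy-5* (161 against 591 and 389) were at least 2-fold below both controls. *col-165* (424 against 44.4 and 165), *dpy-17* (1629 against 53.9 and 696) and the collagen prolyl hydroxylase gene *phy-2* (414 against 116 and 201) were at least 2-fold above both, as were the cuticlin gene *cut-3* (409.9) and *col-74* (277) with the operation-site control at the floor.

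In muscle, thick filament genes had a median of -0.40 with 8 of 11 below both controls, as *myo-1* (296 against 814 and 427), *ttn-1* (135 against 282 and 191) and *unc-22* (81.2 against 195 and 111, but between the controls on a second probe set) were, but *unc-54* (2107) lay between the controls and *myo-3* (306.3) between them too, next to the operation-site value. Attachment and dense body genes showed no shift, with a median of -0.04. Markers of the pharynx had a median of -0.99 from the control mean with 5 of 7 below both controls, *pqn-8* reading 31.9 against 61.8 and 67.9 and *tni-4* 209 against 732 and 292. This median ran from -1.22 to -0.14 over 9 settings of the processing, each control alone included, and was -0.14 against Tsukuba alone. The controls themselves differed on this list. Of these 7 markers, 5 are also members of other lists, so this median is not separate evidence. *unc-120* (135) lay between the controls. *cha-1* did so on one probe set (42.2) and was at the floor on another (54.1 and 50.8 in the controls). *unc-17* (53.7) lay just below them, or between them on another probe set (45.7 against 37.5 and 55.1), though without scaling *unc-17* was 0.15 above them, as *unc-15* was by 0.18 and *mlc-1* by 0.10. By size, 95 genes lay at least 2-fold outside both controls, 28 above and 67 below. Above them were *F22B5.4* (373 against 82.9 and 102), the neuropeptide gene *nlp-39* (524 against 54.9 and 199), *cht-5* (78.9 against 33.3 and 27.5), *set-24* (202 against 89.8 and 91.8, with a second probe set 0.78 above in log2), *nssp-41* (93.7 against 26.7 and 44.8), *cyp-33A1* (359 against 175 and 135) and *clec-52*, at 337 with the operation-site control at the floor. Below them were *F19F10.1* (42.4 against 175 and 140.2), *T20D4.12* (54.3 against 218 and 162), *dach-1* (25.4 against 69.6 and 103.1), *T28A11.19* (51.96 against 139 and 143), *C50D2.6* (28.8 against 76.8 and 76.8), the inositol transporter gene *hmit-1.2* (40.8 against 104.7 and 121) and *H39E23.3* (1274 against 3270.4 and 3442).

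No gene passed limma at an adjusted p under 0.05 in hypergravity, 250 did at the unadjusted threshold where chance gives 503.8, and the smallest adjusted p was 0.948. For *ugt-8* the difference from the control mean was -1.81 ± 0.30 (log2, SE, limma) with an adjusted p of 0.948, below both controls. The Tsukuba control lay 2-fold outside the operation-site control and hypergravity at 55 genes, and the operation-site control outside the Tsukuba control and hypergravity at 586, against the 95 of hypergravity. Of the 52 lists, 16 stood apart, 5 higher and 11 lower. Against the Tsukuba control alone the lists of thick filament (-0.25), insulin-like peptide (-0.29), histone (0.13), early embryo (0.44), pan-neuronal (-0.19) and pharynx genes (-0.14) no longer did, and against the operation-site control alone the thick filament list (-0.32) did not; the 2-fold count was 235 genes against the Tsukuba control alone and 1124 against the operation-site control alone. Without scaling, where the median of all genes was 0.39 higher in hypergravity, 221 genes were higher and 14 lower, centring on the median gave 45 and 47, and the trimmed mean 22 and 89.

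**Figure D3:**
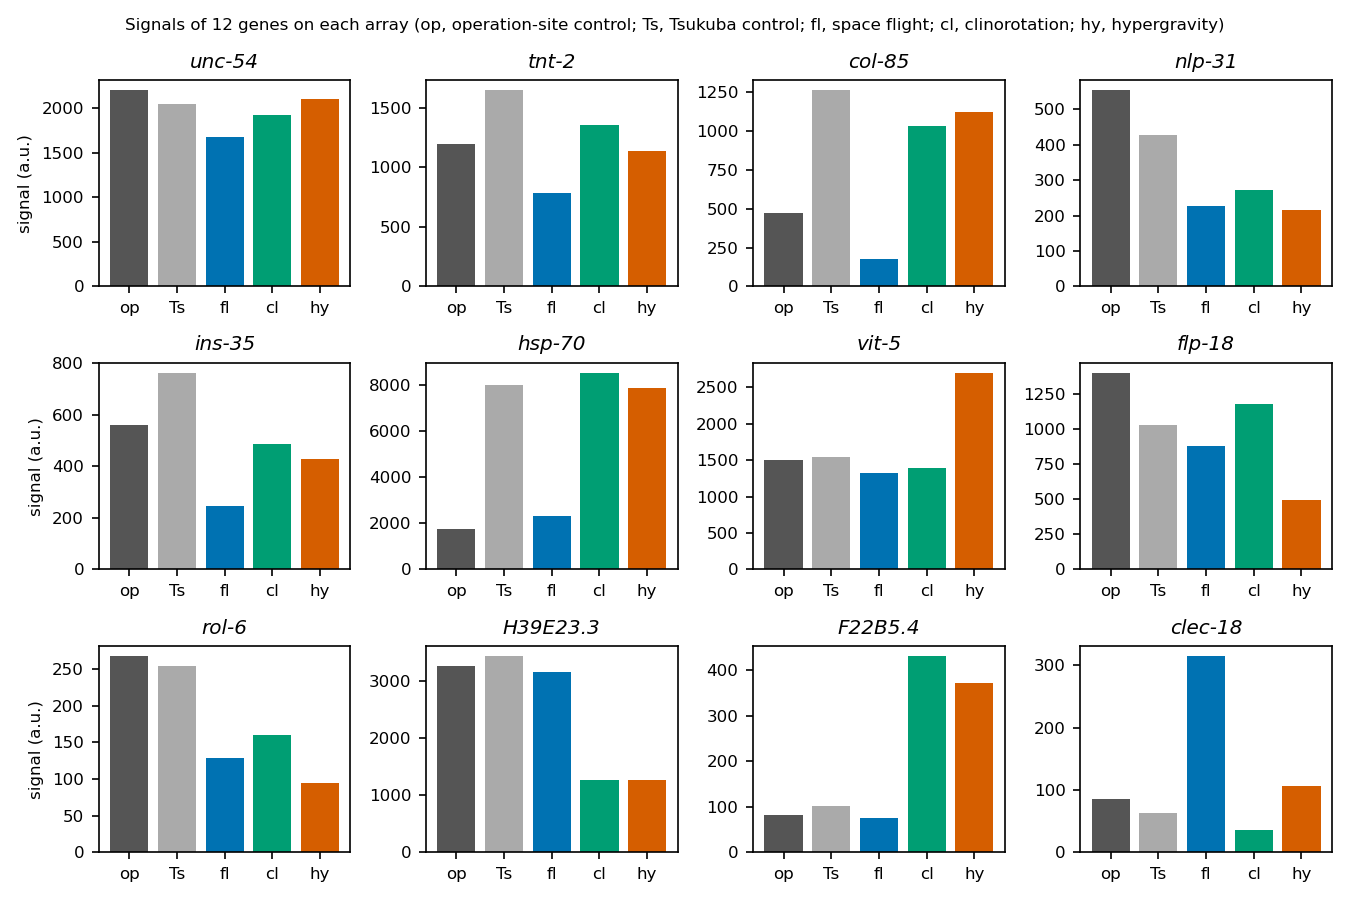
Signals (arbitrary units, linear axes from 0) of 12 genes on the operation-site control, Tsukuba control, space flight, clinorotation and hypergravity arrays, 1 bar per array and no error bars. *unc-54* is lowest in space flight (1673), though not without scaling, *vit-5* highest in hypergravity (2699), and *F22B5.4* higher in clinorotation (432) and hypergravity (373) than on the other arrays.

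Changes shared between conditions were few at 2-fold on scaled signals with the floor. Space flight and hypergravity, the opposite ends of the gravity scale, had 0 genes outside both controls in opposite directions. Independent lists would give 0.16, so this count does not tell whether opposite effects exist. The pair shared 6 genes below both controls, where independent lists would share 0.20: *dach-1*, *Y42A5A.3*, *hmit-1.2*, *sdz-8*, *ugt-8* and *F59E11.5*. *Y42A5A.3* read 103.7 in space flight and 109 in hypergravity against 246 and 245, and *sdz-8* 93.4 and 88.4 against 197 and 201. Space flight and clinorotation shared 2 genes above both controls, *rrn-3.56* and, on 1 of its probe sets only, *T25B9.8*, where independent lists would share 0.0126, and 0 below. Clinorotation and hypergravity shared *F22B5.4*, *F13B12.4*, *C36C5.12* and *clec-223* above both controls and *H39E23.3* and *fbxa-14* below, where independent lists would share 0.0196 and 0.0117. *F13B12.4* read 62.3 in clinorotation and 75.4 in hypergravity against 24.9 and 29.2, and *clec-223* 51.4 and 54.6 with both controls at the floor.

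All comparisons share the 2 controls, and genes differ in spread, so overlap beyond that of independent lists can arise without any change. In 100 sets of arrays simulated without any change, 33.8 genes on average lay above both controls in each condition, 33.6 below in each and 8.7 opposite. Those sets had 273 genes outside both controls per condition, more than measured, so the counts cannot be set side by side. How much of the measured overlap the shared controls and the spread make was not settled. Across genes, differences from the control mean in space flight and clinorotation correlated at r = -0.26, those in space flight and hypergravity at r = 0.06 and those in clinorotation and hypergravity at r = 0.59. Arrays simulated without any change, each gene with its own spread between the controls, gave r = 0.33 over 100 draws. The covariances were -0.04, 0.01 and 0.10 in that order, against a simulated 0.09. Simulated arrays varied independently, whereas the measured arrays lined up along the difference between the controls. The simulated r and covariance are therefore no baseline for the measured ones. With a different control for each condition the correlation was 0.081 or -0.70 for space flight and clinorotation, 0.34 or -0.51 for space flight and hypergravity, and -0.029 or 0.073 for clinorotation and hypergravity, depending on which control went with which condition. Space flight lay nearer the operation-site control, and clinorotation and hypergravity nearer the Tsukuba control. Where each array is set against its farther control, the difference between the controls enters both sides with opposite signs. This alone makes r negative, so -0.70 and -0.51 are no evidence of opposite effects. Differences from the control mean carry part of it too, so neither is the r of -0.26. In clinorotation and hypergravity the difference between the controls enters both sides with the same sign. This raises r, which was -0.029 or 0.073 with different controls, so the r of 0.59 is no evidence of a shared effect.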

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

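The tests of scaling, worm mixture, site and tissue share in this part were chosen only after the results were seen. Signals outside the measured genes appeared among the 1782 probe sets without a single gene name, which the comparisons do not use: 9 lay at least 2-fold beyond both controls in space flight (4 higher, 5 lower), 3 in clinorotation (1 higher, 2 lower) and 11 in hypergravity (6 higher, 5 lower).

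Sperm genes differed between the ground controls by a median of 1.83 (log2), and the space flight array lay near the operation-site control while clinorotation and hypergravity lay nearer the Tsukuba control. Scaling between arrays moves genes of like signal alike. The sperm median exceeded that of random lists of like signal by 1.73 as deposited and 1.80 after quantile scaling, where the central 95% of random lists lay within -0.16 to 0.15. The list had already been picked by a like comparison with random lists. This outcome was therefore nearly fixed beforehand and is no separate test of scaling. A different share of sperm-making worms in these mixed-stage cultures may explain it and stays open: 38 of 43 sperm genes (88.4%) were higher in both the operation-site control and space flight than on each of the other 3 arrays, against 24.2% of all tested genes, but this restates the pattern and is no separate support. Site of culture or array batch cannot be told apart from it, because each site holds 1 control; 888 genes differed 2-fold between the controls, against at most 189 between any array and the one nearest to it. A biological difference between the cultures of both sites remains untested.

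Muscle and cuticle genes were lower in space flight relative to all genes. As deposited, the body wall muscle and collagen medians lay -0.36 and -0.50 from those of random lists of like signal, whose central 95% lay within -0.21 to 0.22 and -0.09 to 0.08. Both lists had been picked by a like comparison with random lists, so this outcome was nearly fixed and is no separate test of scaling. Without scaling the medians of both lists were 0.21 and 0.10 above the control mean and those of the random lists 0.57 and 0.60, so the lower level is relative. A lower share of body tissue against germ line, through more or larger germ lines per worm, may contribute, because germ line genes were higher; it would lower the intestine with the muscle. The intestine median exceeded the body wall muscle median by 0.26, with a 95% interval over genes of -0.01 to 0.49, so the test leaves this open. A different mixture of stages was not tested. The effect of microgravity, which the design names, also remains open and rests on 1 array.

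Neuropeptide genes were lower in hypergravity while yolk and egg genes were higher. After quantile scaling the neuropeptide, vitellogenin and germ line medians lay -0.62, 0.74 and 0.35 from those of random lists of like signal, whose central 95% lay within -0.11 to 0.10, -0.42 to 0.30 and -0.15 to 0.13, and as deposited -0.62, 0.78 and 0.39. These lists too had been picked by a like comparison, so this is no separate test of scaling. An equal fall of all body tissues is argued against as the whole cause on this array. Neuropeptide genes lay below body wall muscle genes by a median difference of -0.41, with a 95% interval over genes of -0.60 to -0.21. That interval runs over genes of 1 array and not over cultures. Body tissues that fall unequally were not tested, so a changed share of tissues stays open. An older or otherwise different mixture of stages was not tested. The effect of hypergravity remains open, with 1 array.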

How the results depend on the processing

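Scaling to a common trimmed mean was the only alternative chosen after the data were seen. The limma count was 0 for each condition under each alternative run (144, 33 and 250 genes at unadjusted p under 0.05 in the fit reported); with a control left out no spread remains and it could not be fitted. The counts of genes 2-fold beyond both controls (70, 15 and 95 in space flight, clinorotation and hypergravity) were 367, 37 and 235 as deposited, where arrays differ in level; for the shifts that follow, the cause was not tested unless stated. With the floor at the 25th percentile they were 141, 100 and 254, and 1617 genes differed between the controls; at the 60th percentile 30, 3 and 42, with 398; and without floor or filter, which lets in every signal however low, 1336, 1405 and 1604, with 4364. By construction, 3-fold gave 6, 1 and 7 and 1.5-fold 529, 243 and 718. Leaving out 1 control, so that 1 comparison replaces a pair, gave 189 to 1073, 56 to 916 and 235 to 1124. Lists standing apart in clinorotation (9) were then 15 to 17. Without floor and filter, r was 0.17 for space flight and clinorotation, which reversed it, 0.22 for space flight and hypergravity and 0.39 for clinorotation and hypergravity. With different controls, first condition against the operation site and second against Tsukuba, r was 0.081, 0.34 and -0.029; the other way round it was -0.70, -0.51 and 0.073. These include the reversals of space flight with clinorotation (0.081), space flight with hypergravity (-0.51) and clinorotation with hypergravity (-0.029). In the pairs with space flight, r was negative (-0.70 and -0.51) where each array was set against the control it lay farther from. The difference between the controls then enters both sides with opposite signs. Clinorotation and hypergravity both lay nearer the Tsukuba control. Their differences from the control mean therefore both hold the difference between the controls with the same sign, which raises r. With different controls their r went from 0.59 to -0.029 or 0.073. Shared genes above both, below both and opposite were 44, 0 and 0 as deposited for space flight and hypergravity (0, 6 and 0 reported), 3, 10 and 0 and 0, 3 and 0 with the 25th and 60th percentile floors and 187, 217 and 69 without floor; for clinorotation and hypergravity (4, 2 and 0) they were 14, 0 and 0, 11, 11 and 0, 1, 1 and 0, and 236, 246 and 55; for space flight and clinorotation (2, 0 and 0) they were 4, 0 and 0, 2, 2 and 0, 0, 0 and 0, and 187, 212 and 73. Of the values for single genes under alternatives 2018 stayed within their spread and 547 moved, and for lists 277 and 66. For lists under the alternative scalings, each array was first centred on the median of its tested genes. Those settings therefore do not test list medians without scaling. As deposited and uncentred, the body wall muscle and collagen medians in space flight were 0.21 and 0.10 above the control mean. Standing apart in every setting run on lists were 6 of the 18 lists of space flight, 6 of 9 of clinorotation and 9 of 16 of hypergravity. Lists were not rerun with the mean over probe sets or without cross-hybridising probe sets. Members read on such probe sets, among them *msp-3*, *his-1*, *vit-4* and *vit-5*, may not be separate measurements. No paired analysis was possible because each condition has 1 array. How far signal near background limits dim genes was not tested, but counts move with the floor.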

Other observations

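The tests for neighbouring genes in this part were chosen only after the result was seen. Ribosomal protein genes (77 measured) had medians of 0.01, 0.01 and -0.01 (log2) from the control mean in space flight, clinorotation and hypergravity, and genes of oxidative phosphorylation (47) 0.06, -0.06 and 0.00. Genes of cholinergic signalling (21) had medians of -0.01, -0.11 and -0.10, those of the insulin/IGF pathway (13) -0.03, 0.04 and -0.06, and those of glycolysis (15) -0.06, 0.00 and 0.10.

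Several heat shock genes differed between the controls. Chosen after its values were seen, *hsp-16.2*, a small heat shock protein gene, read 269.5 in the operation-site control, 6148 in the Tsukuba control, 563 in space flight, 5608 in clinorotation and 5589 in hypergravity, and *hsp-16.41* read 127, 3850.3, 220.1, 3676 and 3664. Small and inducible heat shock genes had medians of 0.12 against the operation site and -0.85 against Tsukuba in space flight, of 1.35 and 0.09 in clinorotation and of 1.55 and -0.02 in hypergravity. In hypergravity *hsp-12.3*, at 2814 against 1423 and 1384, and *hsp-12.6*, at 1896 against 609 and 1058, lay above both controls.

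*F35E8.6* and *F35E8.7*, both higher in space flight, are neighbours on their chromosome. That neighbouring genes change together was tested as a hypothesis: 1 adjacent pair was found among the genes higher in space flight, against 0.0199 on average in random sets (permutation p 0.0195, adjusted for 6 such tests 0.117), which does not pass the correction and leaves the question open.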
